A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

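The series holds 4 chromatin immunoprecipitation (ChIP) experiments on budding yeast (Saccharomyces cerevisiae) cells labelled as lacking HOG1, the gene of the stress-activated protein kinase of the hyperosmotic response. Each was hybridised to 1 Agilent 2-colour tiling array. In ChIP, chromatin is fixed, sheared and pulled down with an antibody, and the recovered DNA is measured along the genome. Per the labels' protocols, chromatin was sheared by sonication and the DNA was amplified by ligation-mediated PCR, so structure finer than the fragments was not resolved. Cy5 carried the DNA recovered with an antibody against histone H3 acetylated at lysine 9 (H3K9ac) or at lysine 14 (H3K14ac). Cy3 carried the DNA recovered with an antibody against H3 itself, from the same strain and condition. Dyes were not swapped, so a dye effect at a probe stays in its level but largely cancels in a difference between 2 arrays. The 4 groups were H3K9ac and H3K14ac, each without stress in rich medium and after 10 min in 0.4 M NaCl, with 1 array per group. Wild-type arrays, which the design text names as the comparison, were not analysed here.

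The labels and the authors' workbook notes disagree on 2 points. The labels give the strain as BY4742, while the notes in the workbooks give BY4741 and a longer crosslinking time. The strain is weighed in the results through the signal over marker genes, and the crosslinking time was not settled.

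The deposited scanner files give spot intensities on a linear scale, and per the file headers they were extracted with Agilent Feature Extraction 10.10.1.1. Per the file headers and the labels, the processed intensities had been background-subtracted, spatially detrended and scaled between dyes by the linear method. Probe positions follow sacCer1, the build the file headers name. The authors' deposited per-gene tables hold log2 ratios that, per the notes in the workbooks, the authors made by normalizing acetylation to H3 and averaging in 100 bp bins around the transcription start site. The base is not given there and was taken from the values, whose spread within bins was close to that of log2 ratios from the same arrays. Which further normalization and which start sites the authors used is not given in the sources used here. The same tables sort genes into NaCl-induced and NaCl-repressed classes, each split into Hog1-dependent and Hog1-independent. How these classes were made is not given in the sources used here, so the classes may rest on data related to these arrays and are not independent evidence of direction. A class differed between the workbooks for 4 genes, and the H3K9ac workbook was followed.

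Each array file held 243504 spots, of which 237908 were probes. Control spots were left out. Spots the scanner software called non-uniform or population outliers on any array (591 probes) were left out on all 4, and saturated spots were kept. Of 236230 nuclear probes, 235671 stayed in, with a median spacing of 44 bp. Of these, 235498 were well above background in both channels on every array. The number of arrays limits the precision. For each probe, log2 of processed Cy5 over processed Cy3 was computed and centred on the array's median over these probes, with no loess or quantile step. A centred ratio shows a change relative to the rest of the genome and cannot show a change shared by all probes.

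Gene names and start codons came from the array files' own annotation. Of 5685 genes named there, 5641 nuclear ones matched a protein-coding gene of the R64 assembly by systematic name, and R64 served only for standard names, gene types and coding lengths. Start codon positions were derived from the probe annotation, and 27.7% had the coordinate of the R64 start within 1 bp. The builds differ, so this does not measure their precision, and positions are given as near. A gene's value is the mean over probes with midpoints from 500 bp upstream to 500 bp downstream of the start codon, for genes with at least 3 probes. This left 5570 genes with a median of 21 probes. Genes whose start codons lie close together share probes. The SD given beside a gene's change is over its probes, which share DNA fragments, and says nothing of variation between cultures.

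With 1 array per group there was no replicate check on any difference, and no p-value was computed. Genes were counted by a fixed size, a difference of at least 0.5 on the log2 scale, with 1 as an alternative. The spread between 2 readings of H3, on the H3K9ac and on the H3K14ac arrays, is the only repeated measure, and both readings may come from 1 immunoprecipitate. A list of genes was described by its median change and by the percentile of that median among 10000 random lists of equal size, matched in 10 bins of the mean level over both arrays of the mark. The percentile describes these arrays and is no p-value. In H3K9ac and H3K14ac alike, medians below percentile 2.5 or above 97.5 are called outside the random lists. A percentile of 0 or 100 means that no random list, or every one, lay below the median.

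Before the data were examined, 19 lists were fixed: osmostress response, glycerol metabolism and transport, general stress (Msn2 and Msn4 targets), trehalose and glycogen, heat shock chaperones, oxidative stress, pheromone and filamentation, cell wall integrity, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial ribosome, RNA polymerase I and III subunits, glycolysis, hexose transport, respiration, amino acid biosynthesis, ion homeostasis, histones, and seripauperins with related cell wall genes near chromosome ends. Lists overlap: 11 genes are shared by osmostress response and general stress, and 11 by general stress and trehalose and glycogen. The pattern that defined cytosolic ribosomal proteins also took in RPP1, a subunit of RNase P, which stayed in since the list was fixed. The genes named were fixed by a rule at the same time. Per mark, it took the 10 highest and 10 lowest changes among genes whose change kept its sign when H3 was taken from the other mark's array in the same condition. To these were added HOG1, STL1, GPD1, CTT1, HSP12, GRE2, ALD3, ENA1 and FUS1, and from each list up to 3 of its highest and its lowest member. A result that this rule selects is not reported here. Other genes named were chosen after their values were seen, and the text says so.

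The alternatives fixed beforehand were normexp background correction with offset 50 on the raw spot and local background signals (which also leaves out the detrending and dye scaling of the processed intensities), loess within each array, no centring, probes well above background alone, the promoter alone (500 bp upstream), the coding region alone, medians over probes, at least 6 probes, H3 from the other mark's array, no H3, equal spread of both arrays of a mark, the authors' deposited table, and random lists not matched on level. The coding region alone took all probes that the array names for a gene downstream of its start codon, with no limit at the stop codon. Its values can therefore cover DNA past the end of the gene. Several choices were made after seeing the data. They were the percentile bounds 2.5 and 97.5, a tolerance of 0.1 for a changed correlation, which lists count as main results, the use of the authors' classes, a setting without saturated probes, matching on the non-stress level, and equal spread for chromosome ends and for the 2 marks together. The rule for deleted segments was also set then. It took 139 probes in unbroken runs from the coding regions of HOG1, HIS3, LEU2, URA3 and MET17 with Cy3 below 1/4 of the nuclear median on all 4 arrays, and left them out of all other values. A run could skip 1 probe and bridged at most 500 bp.

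Before use, the per-gene step was tested on simulated arrays of the real genes and levels, and the list step on random lists of the real changes. For each mark, all 50 genes set at each of 0.7, 1, -0.7 and -1 passed the size of 0.5 (100%), and 0% of 5253 (H3K9ac) and 5251 (H3K14ac) unchanged genes did. Of 100 random lists of 40 genes with their real changes, 2% in H3K9ac and 3% in H3K14ac fell outside the percentile bounds. Of 50 such lists shifted by 0.2, 100% reached percentile 97.5. Noise in the simulated arrays was independent per probe, so these tests cover the arithmetic and not the error of an array. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.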

Results

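Acetylation of histone H3 at lysines 9 and 14, relative to H3 itself, was measured along the genome of hog1Δ yeast with and without 10 min in 0.4 M NaCl. Hog1 is the mitogen-activated protein kinase that hyperosmotic stress activates, and the design set out to compare its deletion with the wild type, which was not analysed here. The 4 arrays (H3K9ac and H3K14ac, each non-stress and NaCl) had no replicates, so no difference has a replicate check, and all changes are NaCl minus non-stress on the log2 scale. Between 99.38% and 99.43% of the probes on each array were well above background in both channels. The H3K14ac non-stress array had 2206 probes saturated in Cy5, against 50 to 584 on the others, and 509 outlier probes, against 23 to 34. Gene values correlated between the 2 marks across genes with r = 0.88 in the non-stress arrays and 0.91 in the NaCl arrays, against 0.70 (H3K9ac) and 0.82 (H3K14ac) between conditions of 1 mark. Arrays that differ in both did not rank lowest throughout. There r was 0.83 for H3K9ac NaCl with H3K14ac non-stress, and 0.57 for H3K9ac non-stress with H3K14ac NaCl. The H3K14ac non-stress array stood apart in Cy3: probes deviated from the mean of the other arrays with an SD of 0.44, against 0.21 to 0.23 for the others. It stood apart in Cy5 too, where its probes correlated with the other arrays with r of 0.81 to 0.83, against 0.90 to 0.95 among those.

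The deletion of HOG1 was seen on all 4 arrays. Over 26 probes in its coding region, on chromosome 12, median Cy3 was between 0.07% and 0.09% of the nuclear median, and Cy5 between 0.07% and 0.43%. These were the coding probes with Cy3 below 1/4 of that median on all 4 arrays, so part of the low Cy3 was set by their choice. The 48 kept probes named for HOG1 downstream of its start codon gave medians of 0.27% to 0.38% in Cy3 and 0.32% to 1.67% in Cy5. Probes dim in Cy3 ran from position 371620 to 372952 (sacCer1). LYS2, an auxotrophic marker that BY4742 lacks, gave 103% to 110% of the nuclear median in Cy3 over 91 probes. MET17, also called MET15, which BY4742 carries, gave 0.07% to 0.09% over 27 coding probes chosen as for HOG1. The 44 kept probes named for it downstream of its start codon gave 0.06% to 0.08%. These 2 loci read opposite to the BY4742 genotype that the labels give, and so argue against that label. Of the 2 strains named, this leaves BY4741, which the workbook notes give. Over coding probes chosen as for HOG1, LEU2 and URA3 gave 2.6% to 4.6% and 4.2% to 6.7% in Cy3. HIS3 was dim at 3 probes between positions 722286 and 722446 of chromosome 15.

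**Figure D1:**
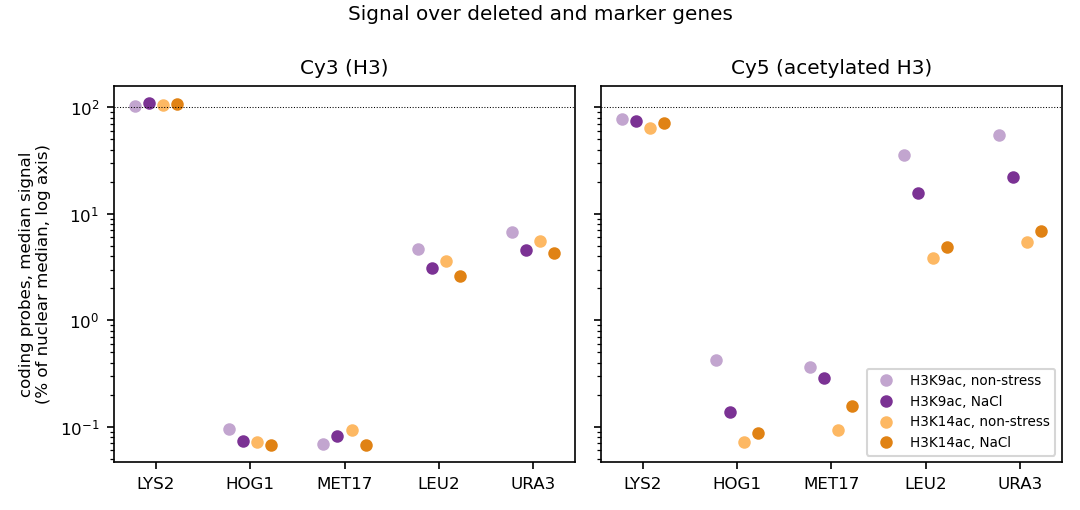
Median signal of coding probes of 5 genes as a percent of the nuclear median (log axis, %) in Cy3 (H3, left) and Cy5 (acetylated H3, right), 1 point per array. Probes of HOG1, MET17, LEU2 and URA3 were chosen as dim in Cy3 on all arrays, and those of LYS2 were not. LYS2 lies near 100% in Cy3, HOG1 and MET17 lie at or below 0.43% in both channels, and LEU2 and URA3 reach 35.4% and 54.9% in Cy5 on the H3K9ac non-stress array.

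Genes of the cytosolic ribosome had the largest difference in H3K9ac between NaCl and non-stress arrays. All 138 measured ribosomal protein genes were lower in the NaCl array by at least 0.5, with a median change of -1.33 (quartiles -1.54 and -1.16), from a median level of 1.73 to 0.36. Random lists matched on the non-stress level, in bins coarse for these genes, also fell, with a median of -0.63. Across all genes the H3K9ac change correlated with the non-stress level, which enters both values, with r = -0.68. RPL12B, which encodes a protein of the large subunit, had the lowest change of all named genes, -2.10 ± 0.43 (SD over 17 probes), from 2.72 to 0.62. Its start codon lies near position 1301604 of chromosome 4 (sacCer1), and its near-identical copy RPL12A, on chromosome 5, changed by -1.87. Among 5570 genes, 848 were lower and 38 were higher in the NaCl array, and 213 were lower and 1 was higher by at least 1. The median over all genes was -0.11 and the SD over genes 0.36.

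The other lowest genes in H3K9ac were also ribosomal protein genes or lay close to them. RPS22A, whose promoter faces RPL39, changed by -1.89, RPL34A by -1.86, RPL30 by -1.85, RPL31B by -1.82, RPL21A by -1.78 and RPL33B by -1.76. BUD20 (-1.81), whose start region also covers that of RPL10, and RFU1 (-1.81), next to BUD20, were the 2 exceptions by name. Several of these genes have near-identical copies, whose DNA can cross-hybridise. RPP1, RPL15B and RPL4A had the smallest differences in the list, -0.58, -0.58 and -0.67.

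Ribosome biogenesis genes, which act in making rRNA and assembling subunits, were lower as well. Of 125, 70 were lower by at least 0.5 and none was higher, with a median of -0.55, and 124 lay below 0. TSR1, a factor of 20S pre-rRNA processing, was lowest (-1.54), and UTP30 (0.06), ENP2 (-0.05) and UTP22 (-0.06) were highest. Of 26 subunits and factors of RNA polymerases I and III, 12 were lower (median -0.48), from RPA43 at -1.15 to RRN9 at 0.21, with RRN11 at -0.03 and RPO31 at -0.16. The medians of all 3 lists lay below every matched random list (percentile 0). Fewer ribosome biogenesis genes were lower over the coding region alone (10, median -0.16), without H3 (37, median -0.39) and in the authors' deposited table (35, median -0.35), and of polymerase genes 6, 5 and 6 were. Glycolysis, amino acid biosynthesis and cell wall genes also lay below the random lists. Of 20 glycolysis genes 10 were lower (median -0.53, percentile 1.3), with PGK1 at -1.08 and PYK2, HXK1 and PFK1 at 0.29, 0.13 and -0.03. Of 44 amino acid biosynthesis genes 13 were lower (median -0.34, percentile 0.4), with LYS21 at -1.05 and ARO3, SER33 and TRP5 at 0.08, 0.03 and -0.02. Of 34 cell wall genes 7 were lower (median -0.27, percentile 0.2), with CWP1, SLT2 and TIR1 at 0.35, 0.25 and 0.16 and the lowest member, MNN1, going from a level of 0.98 to -0.02. Percentiles of glycolysis and amino acid biosynthesis were 14.7 and 7.1 when random lists were matched on the non-stress level, and 20.4 and 9.7 in the authors' deposited table. Glycolysis also lay within the bounds with loess (7.8) and over the promoter alone (16.6), amino acid biosynthesis with H3 from the other mark's array (2.8), and the cell wall list over the promoter (2.9) and without H3 (3.0, median -0.10). Of 10 histone genes 9 were lower (median -0.80, percentile 4.0), from HHT1 at -1.03 to HTZ1 at -0.16, HHO1 at -0.53 and HTB2 at -0.65; HHO1 stood at 0.14 over its coding region alone, and HHT1 has a near-identical copy. The histone list lay below the bounds with normexp (0.02), over the promoter (0.10), with H3 from the other mark's array (0.55), without H3 (0) and without matching (0.02). It lay within them with loess (10.6), in the authors' deposited table (11.7), when matched on the non-stress level (21.1) and over the coding region alone (42.4).

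Few genes had higher H3K9ac in the NaCl array. HSP12, a small membrane-protecting heat shock protein with its start codon near position 107250 of chromosome 6, had the highest change, 1.17 ± 0.18 (SD over 18 probes), from -0.65 to 0.52. Its H3 itself changed by -0.70 on these arrays, so part of this change in the ratio lies in H3. Other genes with high changes were ATG14, of autophagy (0.70), SDH6, an assembly factor of succinate dehydrogenase (0.69), SDS24 (0.69, but -0.03 over its coding region alone), TGL1, a steryl ester hydrolase (0.67), and HFD1, a fatty aldehyde dehydrogenase (0.66). NFI1 (0.61), YNL092W (0.60) and GPM2 (0.59) came next. Most members of the general stress, osmostress and trehalose and glycogen lists stayed within the size of 0.5. Of 56 general stress genes, which answer to the transcription factors Msn2 and Msn4, 5 were higher and 1 was lower, with a median of 0.04 against -0.08 in random lists (percentile 99.9). GAD1 (0.57) and FMP45 (0.54) followed HSP12, and NCE102 was lowest at -0.58. Of 36 osmostress genes, 3 were higher (HSP12, FMP16 at 0.55 and PHM7 at 0.50) and 2 lower, with a median of 0.06 (percentile 99.7, and 97.4, within the bounds, when matched on the non-stress level). GPP1, a glycerol-3-phosphate phosphatase, stood at -0.99. Of 21 trehalose and glycogen genes none passed 0.5 (median 0.04, percentile 97.54), with ATH1 at 0.43, TPS3 at 0.32, PGM2 at 0.29 and TPS1 at -0.50. Over coding regions alone, the medians of general stress and of trehalose and glycogen turned to -0.02 and -0.11, at percentiles 79.1 and 3.9. The trehalose and glycogen list also lay within the bounds without H3 (percentile 89.3), in the authors' deposited table (79.3) and when matched on the non-stress level (92.5).

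The remaining lists lay within the random lists in H3K9ac under the main setting. Their medians and percentiles were -0.12 and 42.3 for heat shock chaperones, -0.13 and 45.8 for glycerol metabolism, -0.12 and 49.8 for oxidative stress, -0.09 and 50.7 for pheromone and filamentation, and -0.12 and 78.9 for the mitochondrial ribosome. They were -0.07 and 24.2 for hexose transport, -0.06 and 86.6 for respiration, -0.03 and 76.3 for ion homeostasis and -0.11 and 12.6 for the 14 measured of 26 seripauperin and related genes. In these lists the highest members were SSE2 (0.32), YPR1 (0.36), CTT1 (0.31), ASG7 (0.45), MRP8 (0.32), GAL2 (0.39), SDH4 (0.55), PMC1 (0.39) and TIR1 (0.16). The lowest were YDJ1 (-0.79), GPP1, SOD1 (-0.93), KAR4 (-0.61), MRPS16 (-0.66), HXT2 (-0.75), ATP14 (-0.58), PMA1 (-0.74) and PAU10 (-0.30). Heat shock chaperones lay below the bounds without H3 (percentile 0.06, median -0.19) and with normexp (0.66, median -0.29). Over coding regions alone pheromone and filamentation (0.56), hexose transport (0.68) and seripauperin genes (0.90) did, the last also when matched on the non-stress level (0.80). Among classical osmostress genes fixed in advance, CTT1, the cytosolic catalase, stood at 0.31, ALD3 at 0.35, GRE2 at 0.17, GPD1 at -0.11, STL1 at -0.15 and ENA1 at -0.37, and the mating gene FUS1 at 0.14. With normexp on the raw signals, which lack the detrending and dye scaling too, 286 genes were higher and 1145 lower, so that higher genes made up 19.99% of those past 0.5 in place of 4.3%. Without the H3 channel 367 genes were lower.

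**Figure D2:**
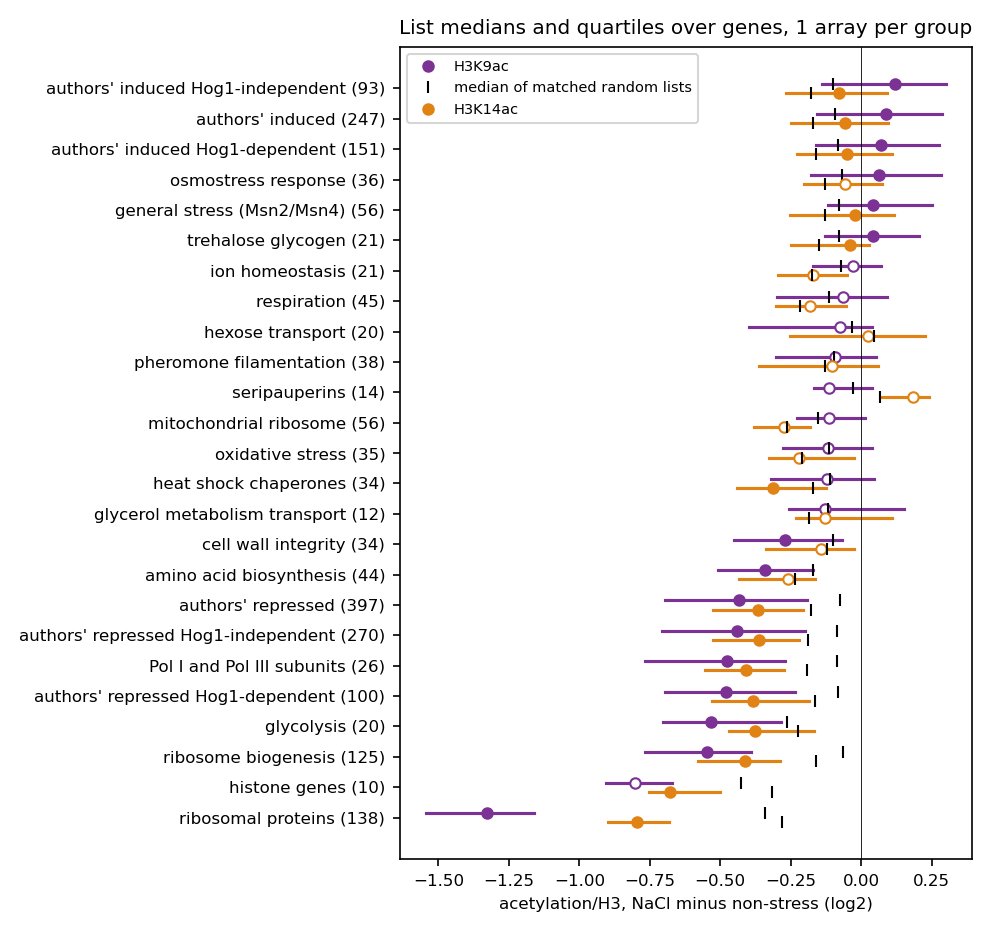
Change in acetylation over H3 (NaCl minus non-stress, log2, x axis) for each list with its number of genes: circles are list medians, lines quartiles over genes, and black ticks the median of matched random lists. Filled circles lie outside the percentile bounds of the random lists, and ribosomal proteins lie lowest, at -1.33 in H3K9ac and -0.79 in H3K14ac.

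In H3K14ac the ribosomal genes again differed most, by less than in H3K9ac. Of 138 ribosomal protein genes 133 were lower by at least 0.5, with a median of -0.79 (quartiles -0.90 and -0.68), from a level of 0.93 to 0.12. Without H3, 28 of them were lower, and with equal spread 94. Random lists matched on the non-stress level also fell, with a median of -0.39. Across all genes the H3K14ac change correlated with the non-stress level with r = -0.76, and with r = -0.23 at equal spread. RPL12B was again lowest (-1.29 ± 0.30, SD over 17 probes), and RPL4A, RPS22B and RPP1 had the smallest differences (-0.28, -0.32 and -0.34). RNH203 (-1.22), a ribonuclease H2 subunit gene beside the rDNA repeats, was followed by the RPS22A and RPL39 pair (-1.14 and -1.11), RPL26A (-1.13), RPL34A (-1.11), RPL9B with the overlapping start region of YNL067W-B (-1.10 and -1.07), BUD20 (-1.08) and RPS14A (-1.07). Of all genes, 599 were lower and 8 were higher, and 22 were lower and 0 higher by at least 1. The median over all genes was -0.22 and the SD 0.24. Scaling both arrays to equal spread left 226 lower genes and moved the median to -0.05, while normexp gave 1844 lower genes and a median of -0.37.

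Ribosome biogenesis genes had a median of -0.41 (47 of 125 lower) and polymerase I and III genes one of -0.41 (8 of 26 lower), both at percentile 0. TSR1 was the lowest of the former (-0.91, but 0.09 over its coding region alone), with UTP22 (0.07), NMD3 (-0.03) and NOP8 (-0.06) highest, and RRN5 (-0.80) the lowest of the latter, with RRN11 (0.05), RRN9 (-0.15) and RPC82 (-0.20) highest. Over coding regions alone the ribosome biogenesis median was 0.07 (percentile 5.4, 6 lower) and that of polymerase genes -0.03 (7.1, 5 lower). Without H3, 11 and 4 genes were lower, with equal spread 24 and 4, and with normexp 79 and 16, and 29 ribosome biogenesis genes were lower in the authors' deposited table and 13 polymerase genes over the promoter alone. Of 10 histone genes 7 were lower (median -0.68, percentile 0), with HTB1 lowest at -0.83 and HHO1, HTZ1 and HHT2 at -0.27, -0.28 and -0.48. Over coding regions alone the histone list lay at percentile 3.9. Of 34 heat shock chaperones 5 were lower and 31 lay below 0 (median -0.31, against -0.22 over all genes, percentile 0.04). SSA2, a cytosolic Hsp70, stood at -0.76, against 0.29 for SSA3 and 0.03 for SSE2, and the list lay within the bounds in the authors' deposited table (percentile 16.3), with loess (5.5), over the promoter (13.2) and with H3 from the other mark's array (2.7). Of 20 glycolysis genes 4 were lower (median -0.37, percentile 0.2), with PGK1 at -0.81 and HXK1, PYK2 and GLK1 at 0.21, 0.18 and 0.14. Under normexp the glycolysis median of -0.27 lay above that of all genes, at percentile 62.7, and the list was within the bounds over the promoter (5.2) and without H3 (17.7).

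The 8 genes with higher H3K14ac were HSP12 (0.93 ± 0.14, SD over 18 probes), PHM7 (0.80), FMP45 (0.68), FDH1 (0.58, over 6 probes), YOR019W (0.58), YNL194C (0.53), YDL199C (0.52) and YMR105W-A (0.52), which shares its start region with PGM2. Part of the HSP12 change again lies in H3, which changed by -0.47 on these arrays. FMP45 and YNL194C encode related membrane proteins of the cell cortex, and FDH1 a formate dehydrogenase with near-identical relatives at chromosome ends. PRR2 (0.49) and SIP4 (0.49) came next. Of the 8, the authors' deposited table classes 6 as induced and Hog1-dependent. General stress genes (3 higher, 4 lower) had a median of -0.02 at percentile 99.9, and trehalose and glycogen genes (4 lower) one of -0.04 at percentile 98.3. NTH1, a neutral trehalase, was the lowest of both (-0.64), and PGM2 (0.44), GDB1 (0.29) and GAC1 (0.29) were the highest of the second. Osmostress genes had a median of -0.06 within the random lists (percentile 95.4), with PHM7, HSP12 and GRE2 (0.39) highest and GPP1 lowest (-0.62). The general stress median was 0.02 with equal spread, and over coding regions alone general stress and trehalose and glycogen lay at percentiles 1.8 and 0.02. With H3 from the other mark's array, without H3 and in the authors' deposited table both lay within the bounds, at 92.2, 93.5 and 81.7 for general stress and 72.1, 60.0 and 91.8 for trehalose and glycogen. The latter did so with normexp (87.8) and equal spread (74.7) too, and the osmostress list passed the upper bound with normexp (99.4), without H3 (99.6), with equal spread (98.0) and without matching (99.98).

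The other lists lay within the random lists in H3K14ac under the main setting. Medians and percentiles were -0.13 and 82.3 for glycerol metabolism, -0.22 and 39.1 for oxidative stress, -0.10 and 73.3 for pheromone and filamentation, and -0.14 and 28.6 for the cell wall. They were -0.27 and 35.7 for the mitochondrial ribosome, 0.02 and 35.0 for hexose transport, -0.18 and 85.7 for respiration, -0.26 and 24.0 for amino acid biosynthesis, -0.17 and 53.8 for ion homeostasis and 0.18 and 96.6 for seripauperins. The seripauperin median turned to -0.06 with equal spread, and the list passed the upper bound without H3 (99.5) and without matching (100). Without matching, pheromone and filamentation (99.6) and hexose transport (100) passed it too. Over coding regions alone the cell wall list (0.13) and hexose transport (1.7) lay below the bounds and respiration above (99.2), and in the authors' deposited table the cell wall list (1.2) and hexose transport (0.57) lay below. Amino acid biosynthesis lay below over the promoter (0.68) and with H3 from the other mark's array (0.52), and oxidative stress above over the promoter (99.7) and without H3 (97.66). The highest members were STL1 (0.25), the peroxisomal catalase CTA1 (0.41), ASG7 (0.30), CWP1 (0.30), MRP8 (0.08), HXT13 (0.41), LSC2 (0.13), GCN4 (0.18), PHO89 (0.44) and PAU20 (0.39). The lowest were GPP1, SOD1 (-0.63), KAR4 (-0.66), MNN1 (-0.74), MRPL6 (-0.57), HXT2 (-0.54), ATP14 (-0.51), LYS4 (-0.76), PMA1 (-0.34) and PAU17 (-0.21). HXT13 and the PAU genes have near-identical copies. CTT1 stood at 0.10, ALD3 at -0.02, ENA1 at -0.07, FUS1 at -0.09 and GPD1 at -0.20.

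Along the gene, the largest difference of the ribosomal lists lay next to the start codon. In ribosomal protein genes mean H3K9ac in the first 100 bp of the coding region was 2.22 in the non-stress array and 0.39 in the NaCl array, and H3K14ac was 1.24 and 0.20. Between 900 and 1000 bp downstream the change was -0.27 and -0.21. In ribosome biogenesis genes the change was -0.91 in the first 100 bp for H3K9ac and -0.67 in the 100 bp upstream of the start codon for H3K14ac. H3K14ac was higher in the NaCl array by 0.23 in these genes from 900 to 1000 bp. For all genes, levels in the first 100 bp were 0.60 and 0.34 for H3K9ac and 0.55 and 0.26 for H3K14ac, while the lowest changes lay from 400 to 300 bp upstream for H3K9ac (-0.26) and from 200 to 100 bp upstream for H3K14ac (-0.32). The osmostress list had its highest change in H3K9ac, 0.12, from 200 to 100 bp upstream, but from 300 to 400 bp downstream after loess. After loess, the peak of all genes and of these ribosomal lists lay up to 200 bp upstream of the start codon, as did the largest H3K14ac differences of the ribosomal lists.

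**Figure D3:**
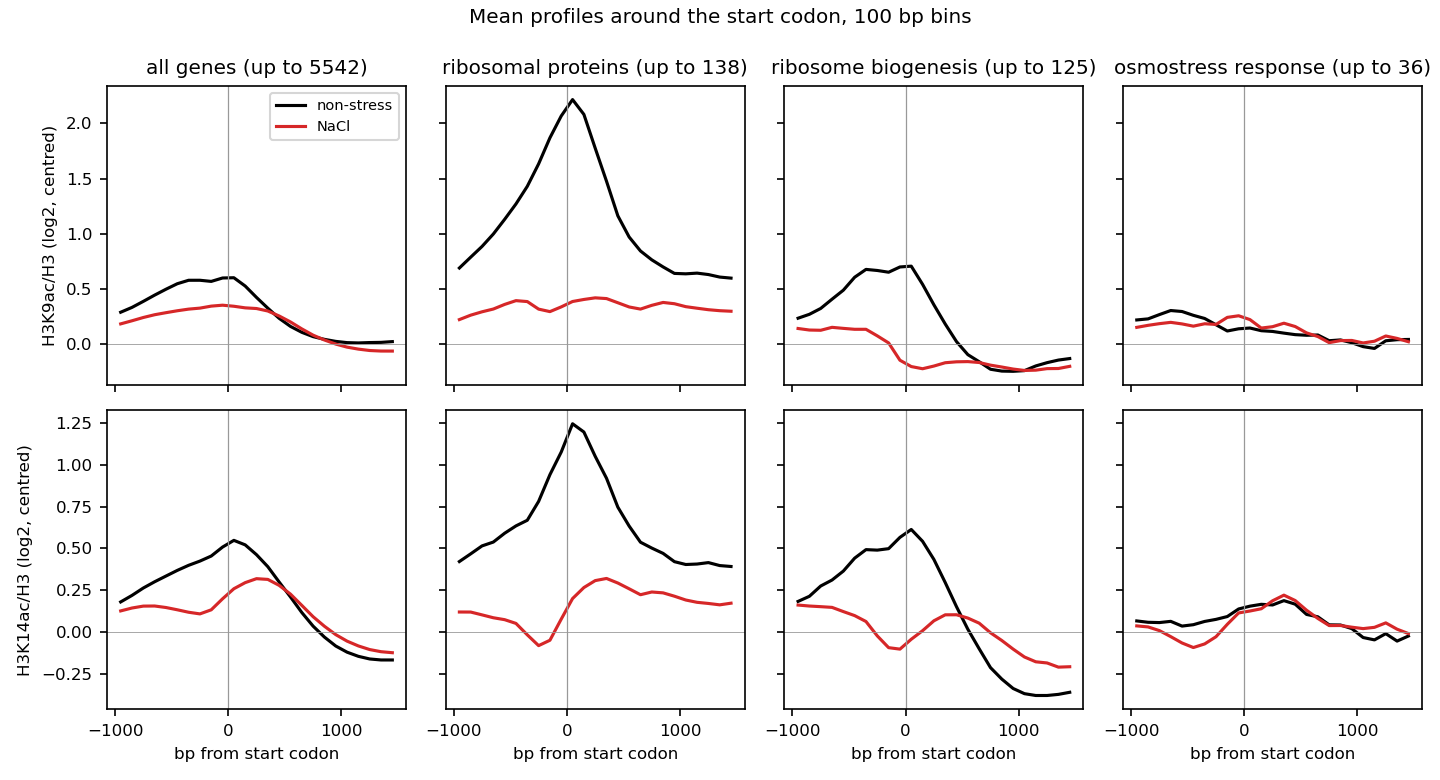
Mean log2 acetylation over H3 (y axis, centred) in 100 bp bins from 1000 bp upstream to 1500 bp downstream of the start codon (x axis, bp), non-stress in black and NaCl in red, H3K9ac above and H3K14ac below. Ribosomal protein genes peak at 2.22 in H3K9ac without stress and lie at 0.39 in the same bin in NaCl, while the osmostress list reaches at most 0.30 in H3K9ac without stress.

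The 2 marks differed between conditions in much the same genes. Across 5570 genes, which are not independent replicates, the changes correlated with a Pearson r of 0.81 and a Spearman rho of 0.77. In both marks 534 genes were lower, against 91.2 for independent lists, among them 133 ribosomal protein genes and 44 ribosome biogenesis genes. HSP12, FMP45, PHM7 and YDL199C were higher in both, against 0.0546 for independent lists, and no gene passed 0.5 in opposite directions, while 3 were lower in H3K9ac and higher in H3K14ac with H3 exchanged between the marks' arrays. Both marks may share 1 H3 immunoprecipitate and the same cultures, so part of the correlation may be technical. With H3 exchanged between the marks' arrays r was 0.69, without H3 0.66, and without H3 113 genes were lower in both.

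**Figure D4:**
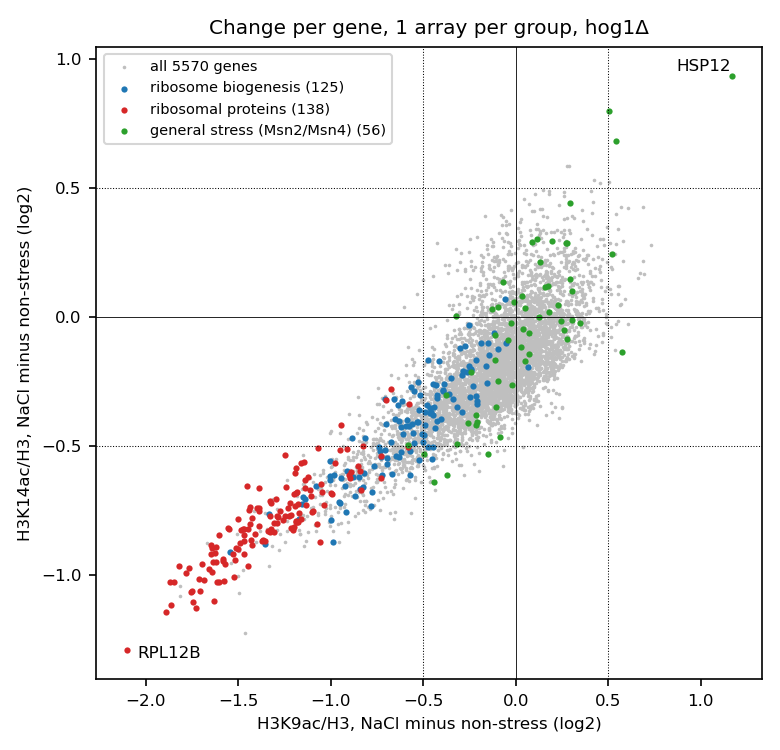
Change per gene (NaCl minus non-stress, log2) in H3K9ac (x axis) and H3K14ac (y axis), 1 point per gene, with dotted lines at 0.5 and -0.5. Ribosomal protein genes (red) lie at the lower left, with RPL12B at -2.10 and -1.29, and HSP12 lies at 1.17 and 0.93.

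H3 itself differed at a smaller set of genes. The Cy3 change was read once on the H3K9ac arrays and once on the H3K14ac arrays, and the readings correlated across genes with r = 0.74. Their SDs over genes were 0.17 each, and the SD of their difference was 0.12. Ribosomal protein genes had higher H3 in the NaCl arrays, with medians of 0.49 and 0.43. In both readings 59 genes were higher by at least 0.5, 35 of them ribosomal protein genes, and SSA1 alone, a cytosolic Hsp70 gene named after its value was seen, was lower (-0.77 and -0.83), a count that was 0 under normexp. HSP12 stood at -0.70 and -0.47 and GPD1 at -0.36 and -0.35. Under normexp 4 genes were higher in both. Without H3 the ribosomal protein medians were -0.77 in H3K9ac and -0.38 in H3K14ac, still below every random list (percentile 0).

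The authors' classes of NaCl-responsive genes, which may not be independent of these arrays, were compared with random lists. Genes classed as induced and Hog1-dependent (151 measured) had a median H3K9ac change of 0.07, and those classed as induced and Hog1-independent (93) one of 0.12, both above every random list. In H3K14ac the medians were -0.05 and -0.08, also above every random list, and both turned to 0.05 with equal spread. Of the 247 induced genes 150 lay below 0 in H3K14ac, with 6 higher and 19 lower by at least 0.5, and in H3K9ac 20 were higher and 20 lower. The median over all genes was -0.22 in H3K14ac and -0.11 in H3K9ac, so most genes of any kind lay below 0. Of the induced Hog1-dependent class 11 genes and of the Hog1-independent class 9 were higher in H3K9ac, and 9 and 11 were lower. In H3K14ac 6 and 0 were higher and 8 and 11 were lower. The difference between the 2 induced classes lay at percentiles 22.3 (H3K9ac) and 84.3 (H3K14ac) among 10000 random reassignments of their genes, so they were not separated. Genes classed as repressed (397) had medians of -0.43 and -0.37 (percentile 0 in both), and of these 171 and 112 were lower, against 53 and 32 over the coding region alone, 90 and 36 without H3, 112 and 95 in the authors' deposited table, and 57 with equal spread and 200 with normexp in H3K14ac. The list overlaps the ribosome biogenesis list in 94 genes and the ribosomal protein list in 9. Without the ribosome biogenesis and ribosomal protein lists the remaining 294, which still held 10 polymerase genes, had medians of -0.36 and -0.33, still at percentile 0. Repressed Hog1-dependent (100) and Hog1-independent (270) genes had H3K9ac medians of -0.48 and -0.44 and H3K14ac medians of -0.38 and -0.36, and their differences both lay at percentile 21.6. Over coding regions alone, the H3K9ac median of the induced Hog1-independent class was -0.01 (percentile 95.4), and in H3K14ac the induced Hog1-dependent and Hog1-independent classes lay within the random lists (percentiles 81.4 and 25.4).

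The series title names Sas2 and Rpd3, which are known to act at chromosome ends, so probes within 30 kb of the 32 ends were compared with all others. In H3K9ac the ends differed from the rest by -0.05, with an SD over ends of 0.09, and 7 of 32 ends lay above the rest. In H3K14ac the difference was 0.02, with an SD of 0.06, and 18 ends lay above; with equal spread it turned to -0.03, with 7 ends above. Without H3 the differences were -0.12, with 1 end above the rest, and -0.06, with 4 ends above. In H3K9ac and H3K14ac they were -0.09 and 0.0004 within 10 kb of 28 ends, -0.05 and 0.03 within 50 kb, and -0.03 and 0.03 within 30 kb after loess. No test of these differences was made.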

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

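All tests in this part were chosen after the signal had been seen. Probes of LEU2 and URA3 gave signal above that of HOG1 and MET17 in both channels, outside the comparisons of this series. They were dim in the H3 channel, and brighter in the acetylation channel on the H3K9ac arrays. Over 22 LEU2 coding probes chosen as dim in Cy3 on all arrays, median Cy5 was 35.4% of the nuclear median on the H3K9ac non-stress array, 15.9% on the H3K9ac NaCl array, 3.85% on the H3K14ac non-stress array and 4.86% on the H3K14ac NaCl array. Over 14 URA3 coding probes chosen in the same way it was 54.9%, 22.1%, 5.43% and 6.95% in the same order. Cy3 stayed between 2.6% and 6.7% for both genes, against 0.07% to 0.09% for HOG1 and MET17. On the H3K14ac non-stress array Cy3 was close to Cy5, at 3.62% for LEU2 and 5.56% for URA3.

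A strain that carries all the deleted genes, mixed in at a low share, would raise HOG1 and MET17 as well. Over their dim coding probes, however, the higher of these reached 0.426% of the nuclear median in Cy5 on the H3K9ac non-stress array. Chromatin of the genomic LEU2 locus would light up the deleted segment on both sides of the coding region, and there Cy5 was 0.241%. Scanner background was not the source, since 100% of the LEU2 coding probes were well above background in Cy5 on that array. DNA that carries LEU2 and URA3 sequence without the genomic flank of LEU2, such as plasmid DNA, may be the source and stays open, as it was not tested. URA3 gives no such contrast, since 4 probes of its deleted segment outside the coding region also read 34.9%, and no biological explanation was tested.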

How the results depend on the processing

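No paired analysis was possible because each group had 1 array and no difference came from a test. Matching on the non-stress level and all settings of the authors' classes were chosen after seeing the data. Among values that answer a comparison, 180 alternatives counted as unchanged and 39 moved the value. Another 4 took it past the percentile bounds, 4 took it back within them and 9 reversed it. A reversal is a changed sign or a changed side of the random lists. For named genes 2259 were unchanged, 121 no longer passed the size, 49 newly passed it, 1 moved and 3 reversed. For the other lists the counts were 325 unchanged, 25 back within the bounds, 24 past them and 6 reversed. Counts of genes within a factor of 1.5 were called unchanged. Sign changes of lists within the bounds, or of genes that did not pass the size, were not counted as reversals. Unchanged therefore does not mean that the sign was kept. In H3K14ac the osmostress median went from -0.059 to 0.0081 over the coding region. STL1 in H3K9ac went from -0.15 to 0.048 with H3 from the other mark's array. Leaving out dim probes (849 and 600 lower genes in place of 848 and 599) tests little, since nearly all of the 235671 probes stayed in (235498). Normexp on the raw signals moved counts far more, and it changes background correction, detrending and dye scaling together. The causes were not tested, except that a larger size passes fewer genes by construction.

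Genes higher in H3K9ac (38) numbered 286 with normexp, 20 with loess, 69 without centring, 62 over the promoter alone, 25 over the coding region alone and 1 at size 1. Genes lower in H3K9ac (848) numbered 383 over the coding region, 367 without H3, 544 in the authors' deposited table and 213 at size 1. Genes higher in H3K14ac (8) numbered 5 with loess, without centring, over the coding region and in the authors' deposited table, 14 with medians over probes, 31 with H3 from the other mark's array, 21 without H3 and 0 at size 1. Genes lower in H3K14ac (599) numbered 1844 with normexp, 921 without centring, 1179 over the promoter, 257 over the coding region, 187 without H3, 226 with equal spread and 22 at size 1.

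The correlation of the marks (0.81) was 0.69 with H3 from the other mark's array, 0.66 without H3 and 0.70 with normexp. Genes lower in both marks (534) numbered 113 without H3, 928 with normexp and 222 with equal spread, and genes higher in both (4) numbered 2 with H3 from the other mark's array, 8 with normexp, 2 with loess and 7 with equal spread. With normexp, 17 genes had higher H3 on the H3K9ac arrays, 6 on the H3K14ac arrays and 4 on both. The chromosome ends differed by -0.057 in H3K14ac without H3 and by -0.028 with equal spread, against 0.018.

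Osmostress genes in H3K9ac (0.065) were at percentile 97.4 when matched on the non-stress level. In H3K14ac they passed the upper bound with normexp (-0.088, percentile 99.4), without H3 (0.019, 99.6), with equal spread (0.0052, 98.0) and without matching (-0.059, 99.98). General stress genes over the coding region were at -0.019 (79.1) in H3K9ac and -0.051 (1.8) in H3K14ac. In H3K14ac they were within the bounds with H3 from the other mark's array (-0.019, 92.2), without H3 (-0.060, 93.5) and in the authors' deposited table (-0.067, 81.7), and at 0.023 with equal spread. Over the coding region, trehalose and glycogen genes were at -0.113 in H3K9ac and -0.089 in H3K14ac, and ribosome biogenesis genes at 0.068 in H3K14ac. Glycolysis in H3K14ac was at -0.27 with normexp.

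Over the coding region, the authors' induced class was at 0.022 (percentile 68.4) in H3K14ac, its Hog1-dependent part at 0.018 (81.4), its Hog1-independent part at -0.0099 (95.4) in H3K9ac and 0.020 (25.4) in H3K14ac, and repressed Hog1-independent genes at 0.0059 in H3K14ac. With equal spread the induced class and its Hog1-dependent part were at 0.050 in H3K14ac and the Hog1-independent part at 0.051. Over the coding region SDS24 was at -0.028 and HHO1 at 0.14 in H3K9ac, and TSR1 at 0.090 in H3K14ac.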

Other observations

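The tests on ribosomal protein genes and on H3K14ac outside the ribosome lists were chosen after the results were seen, as were the genes named here, while the test of the neighbours of ribosomal protein genes was set beforehand. The genes outside the lists that follow were picked as examples, and no enrichment was tested. Some may share probes with a ribosomal protein gene beside them, as BUD20 does with RPL10. FTR1, the high-affinity iron permease, changed by -1.67 in H3K9ac and -0.88 in H3K14ac, and its H3 was higher by 1.12 and 0.76. FRE1, a ferric reductase, stood at -0.91 and -0.54, with H3 at 0.84 and 0.99. At FTR1 and FRE1 most of the change in the ratio thus lies in higher H3. For FRE1 on the H3K14ac arrays the rise in H3 was larger than the fall in the ratio. EFT2, for a translation elongation factor, went from a level of 2.28 to 0.78 in H3K9ac and from 1.12 to 0.12 in H3K14ac, while its near-identical copy EFT1 went from 1.13 to 0.55 and from 0.54 to 0.20. GUA1, of GMP synthesis, stood at -1.54 and -0.91, RKI1, of the pentose phosphate pathway, at -1.47 and -0.98, the phosphate regulator PHO4 at -1.50 and -0.84, and TOD6, a repressor of ribosome biogenesis genes, at -1.33 and -0.96.

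Most genes higher by 0.5 in H3K9ac stayed below that size in H3K14ac, since 4 of 38 passed in both. ATG14, ATG40 and ATG34 stood at 0.70, 0.58 and 0.54 in H3K9ac and at 0.17, 0.29 and 0.24 in H3K14ac. SDH6 and SDH4, an assembly factor and a subunit of succinate dehydrogenase, stood at 0.69 and 0.55 in H3K9ac and at 0.22 and 0.09 in H3K14ac. The subunit genes SDH1, SDH3 and SDH2 did not pass 0.5 in H3K9ac, at 0.36, 0.17 and -0.08, and stood at 0.11, -0.12 and -0.04 in H3K14ac. These genes too were picked as examples, and whether the marks differ at them was not tested.

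Lower H3K9ac of ribosomal protein genes in the NaCl array was set against 3 technical explanations, and H3K14ac was not put to these tests. Compression of the whole ratio scale would keep the order of genes, but their median rank among all genes in H3K9ac went from percentile 97.8 to 51.7; an earlier test, against random lists matched on the non-stress level, pointed the same way and was replaced because its level bins are coarse for these genes. Saturated spots did not carry the difference, since 138 of 138 genes were still lower without saturated probes, though just 27 of 2677 probes were saturated. The H3 channel alone did not carry it either, since without H3 the list lay at percentile 0 in H3K9ac. Outside these tests, the median rank of the list in H3K14ac went from percentile 92.0 to 32.1. Without H3 the list also lay at percentile 0 in H3K14ac, with 28 of 138 genes lower by at least 0.5. A difference between single cultures, immunoprecipitations or amplifications, and a response to NaCl in cells without Hog1, stay open.

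Outside the ribosome and polymerase lists, 411 genes were lower in H3K14ac, and 104 were with equal spread of both arrays, while in H3K9ac the counts were 628 and 673. A wider ratio scale on the H3K14ac non-stress array than on the H3K14ac NaCl array may thus account for much of the H3K14ac count. Equal spread alone cannot tell a stretched non-stress array from a compressed NaCl array. Equal spread would also remove a true loss shared by many highly acetylated genes, so that stays open. The H3K14ac non-stress array, which stood apart in Cy3 and Cy5, enters every H3K14ac difference. Its ratio scale was the widest, with a median absolute centred log2 ratio of 0.53, against 0.34 to 0.40 on the others. The H3K14ac NaCl array, at 0.34, lay nearer to the H3K9ac arrays, at 0.39 and 0.40. The non-stress array thus departed from these more than the NaCl array did.

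A further hypothesis was that divergent neighbours of ribosomal protein genes have lower acetylation beyond the reach of the ribosomal protein gene's own start region. The probes used were those named for a neighbour downstream of its own start codon, with no limit at its stop codon. Over such probes more than 1000 bp from the ribosomal protein gene's start codon, 58 neighbours had a median H3K9ac change of -0.19. Random lists had -0.04 (percentile 0), and the H3K14ac change was -0.06 against 0.05. By the rule set beforehand this would have excluded reach. That rule did not allow for reach past 1000 bp. The mean profile of ribosomal protein genes still changed by -0.47 in H3K9ac between 900 and 1000 bp upstream, more than the neighbours' median. This profile averages genes with and without a divergent neighbour and can cover the neighbours' own DNA. It cannot show how far reach extends either. Reach and a change of the neighbours' own therefore cannot be told apart.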
